A study of Mus musculus with 4 samples.

How the data were processed

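Per the labels' protocols, total RNA was taken with columns from hematopoietic stem and progenitor cells that had been purified by cell sorting, and libraries followed a standard Illumina procedure. The sort markers, the tissue, and the age and number of the animals are not given in the sources used here. The series holds 4 RNA-seq libraries, 2 from control mice and 2 from caNIK mice. In caNIK mice, a form of the kinase NIK that escapes its negative regulator TRAF3 was placed behind a removable stop at the Rosa locus, and the stop was removed in blood cells by the Cre recombinase of the Vav-iCre line. Groups and replicate numbers were taken from the sample titles.

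The authors deposited 1 table of whole-number read counts per gene symbol for each library, with no normalization, per the file headers and the values. The submitters' processing notes name FastQC, TopHat2 2.1.0, featureCounts 1.5.0 and DESeq2 1.10.1, with no role or order, and the genome build mm9. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads from near-identical gene copies and from overlapping or antisense genes therefore cannot be told apart. Among the genes named, this bears on the MHC, globin, Gbp, Oas, Ly6, Birc, Ifitm, serpin, tryptase and chymase families, and on Csf2rb2 and Apol11b. Each table lists the same 24015 symbols. Of these, 22508 were found as current symbols, and 23876 as current symbols or synonyms, in a RefSeq gene table of GRCm38. That build differs from mm9, so no coordinates are given.

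Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups, which left 14191, and library sizes were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model with group as its only term was fitted (glmQLFit) and tested with the two-sided F test (glmQLFTest). A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are caNIK against control and stand with their standard errors (SE), taken from the F statistic. Levels are TMM-normalised CPM (counts scaled to a common library size), given as mean ± SD over n = 2 libraries. Gene lists were tested with limma 3.58.1 camera, which compares the members of a list with all other tested genes, at a preset inter-gene correlation of 0.01. Lists with at least 5 tested genes entered, and p-values were adjusted over all 29 lists together.

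The 23 functional lists, the 6 lists of cell type markers, the sex-linked genes, the tests and the rule for named genes were fixed before the data were examined. The rule took Map3k14, then the 8 largest rises and the 8 largest falls. These had to pass the threshold, with no overlap of CPM between groups, a mean of at least 5 CPM in the higher group and a symbol that is not of a predicted gene or clone. From each list with members past the threshold it took the 2 with the smallest p, or 3 where 6 or more passed. Nfkb2, Relb, Birc3 and Traf3 were named in any case. The rule gave 88 distinct genes, of which some are not reported here, and any other gene named was chosen after its values were seen. Among those are the members of 6 further lists: epithelial structural genes, mature B cell identity genes, genes cited as AIRE-dependent in thymic epithelium, fetal HSC and fetal liver progenitor genes, embryonic globin genes, and co-stimulatory and checkpoint ligands.

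Library totals lay between 18574452 and 23162766 counts. Where a gene had no count in either library of a group, its fold was computed against 3 counts over the group and is a lower bound. Where it had 1 to 3 counts, the ratio stands with an exact 95% interval. These bounds and intervals cover counting error only.

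The test was tried on simulated counts made for caNIK against control from the real means, library sizes and dispersion trend, with 200 genes changed in each of 5 simulations. Far more genes, 3129, passed in the data, so recovery there may differ. Of the changed genes, 4.78% were recovered at 1.5-fold, 36.4% at 2-fold and 76.1% at 4-fold, with a median of 13926 genes tested. Of all calls, 1.77% were of unchanged genes. A simulated list of raised genes was called in 5 of 5 simulations and a list of unchanged genes in 0 of 5. Simulated genes were drawn independently of each other, so this does not test camera on correlated genes. In the real lists the estimated correlation reached 0.93 (mitosis and G2/M).

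Alternatives were DESeq2 1.42.0 (Wald test), limma-voom, median-of-ratios or upper-quartile factors or library totals in place of TMM, other filters (at least 1 read in any library, or at least 1 or at least 5 CPM in 2 libraries), the replicate number as a block, each library left out in turn, and a test against a fold change of 1.5 (glmTreat). For lists they were camera with a correlation estimated per list, the self-contained test fry, and part of the same scalings, filters and left-out libraries. With an estimated correlation, camera takes its test on the residual degrees of freedom, which are few in this design. That setting therefore has little power here, and a list that fails it is not shown to be unchanged. List medians without 1 library were chosen after the data were seen. Where a left-out library leaves 1 in a group, that library is assumed to vary like those of the other group.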

Results

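RNA-seq read counts were available for 4 libraries of sorted mouse hematopoietic stem and progenitor cells (HSPC). They came from 2 control samples and 2 caNIK samples, in which a TRAF3-resistant form of NIK, the kinase that starts non-canonical NF-kB signalling, was switched on in blood cells. The comparison asks how constant NIK activity changes the transcripts of these cells, with the self-renewal of stem cells as the study's stated interest. Totals were 18656529 and 23162766 counts in control replicates 1 and 2, and 18574452 and 21825077 in caNIK replicates 1 and 2. Log2 CPM correlated across genes at 0.972 between the control libraries and 0.974 between the caNIK libraries, against 0.839 to 0.861 between groups. The first principal component held 83.5% of the variance and separated the groups. The second held 10.1% and separated replicate 1 from replicate 2 in both groups. Counts of the control pair differed by more than sampling noise (chi-square per degree of freedom 23.5), as did those of the caNIK pair (42.4). The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical. In control replicates 1 and 2, Xist, transcribed in female cells, lay at 1970 and 903 CPM. The Y-linked genes went the other way (Uty 5.34 and 17.7 CPM), which argues against repeat libraries of the same RNA for the control pair.

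Map3k14, which encodes NIK, was counted 582 and 588 times in the control libraries and 3305 and 3989 times in the caNIK libraries. Its level was 27.6 ± 3.63 CPM in control and 185 ± 10.5 CPM in caNIK (SD, n = 2), a log2 fold change of 2.74 ± 0.17 (SE; edgeR adjusted p = 0.00023). The counts do not separate reads of the inserted copy from reads of the native gene.

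Most tested components of the non-canonical NF-kB pathway and most tested NF-kB target genes were higher in caNIK HSPC. The lists are not separate evidence, since both hold Nfkb2, Relb, Birc3 and Cd40. The pathway list also holds Map3k14, the gene of the inserted kinase. Nfkb2, whose p100 product is processed to p52 in this pathway, rose from 22.2 ± 0.729 to 734 ± 166 CPM, and its partner Relb from 7.09 ± 1.35 to 163 ± 15.3 CPM. Their log2 fold changes were 5.05 ± 0.22 and 4.53 ± 0.21 (edgeR adjusted p = 8.2e-05 and 9.5e-05). Birc3 and Birc2, the ubiquitin ligases that act with TRAF3 to have NIK degraded, rose by 2.97 ± 0.16 and 2.22 ± 0.19 on the log2 scale, and Traf3 itself by 1.08 ± 0.15. Of 16 tested pathway components, 12 were higher, 1 was lower and 3 did not pass (13 and 2 adjusted over the list alone), with a median log2 fold change of 1.36. The member that fell was Ltbr, the lymphotoxin beta receptor. Of 45 tested NF-kB target genes, 30 were higher and 0 lower (34 and 1 adjusted over the list alone), with a median of 2.27. Both lists were higher than other genes by camera (adjusted p = 2.9e-14 and 4.4e-22). With an estimated correlation, these were adjusted p = 0.44 and adjusted p = 0.43. Cd40 was counted in neither control library and was at least 200-fold higher in caNIK; with it at that bound both medians were the same.

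**Figure D1:**
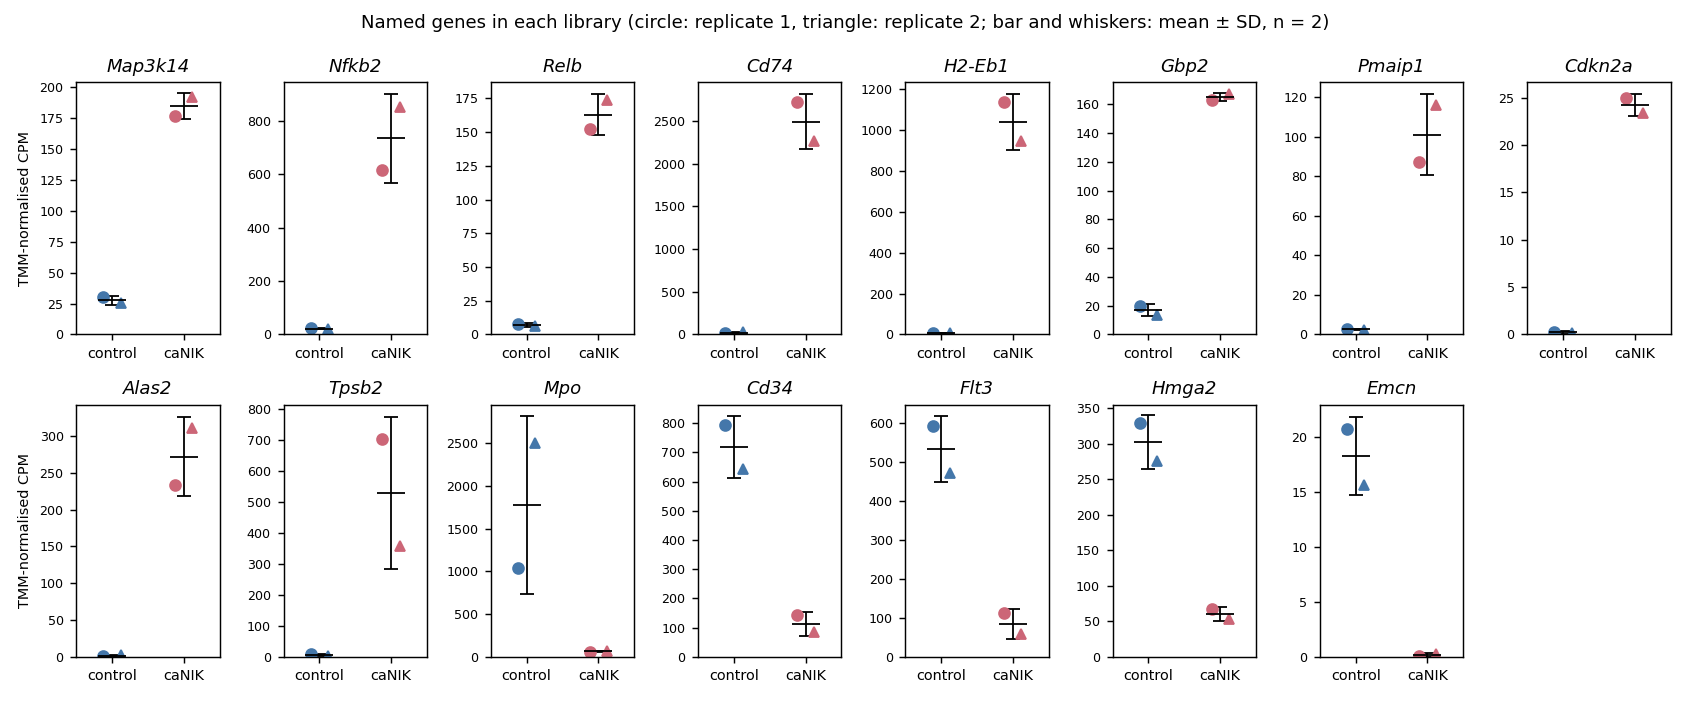
TMM-normalised CPM of 15 named genes in each of the 4 libraries, on a linear axis from 0 for each gene. Circles are replicate 1 and triangles replicate 2 of the control (blue) and caNIK (red) groups, and bars with whiskers show mean ± SD (n = 2). Map3k14 lay at 27.6 ± 3.63 CPM in control and 185 ± 10.5 CPM in caNIK, and the Mpo level differed most between the control libraries (SD 1040 CPM around 1770 CPM).

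Over all genes, 3129 of 14191 passed the threshold in edgeR's quasi-likelihood test, 1964 higher and 1165 lower in caNIK. Changes of 4-fold or more were found for 1138 of the higher and 263 of the lower genes. Among the higher genes, 161 had no read in either control library, and among the lower genes 10 had none in either caNIK library. The largest rises included 7 such genes. These were Serpinb9b, a serine protease inhibitor (at least 2350-fold higher), the embryonic globin Hbb-y (at least 2030-fold), the neural adhesion gene Cntn1 (at least 1850-fold), the secreted protease Pappa2 (at least 1210-fold), the photoreceptor gene Rcvrn (at least 925-fold), Apol11b (at least 608-fold) and the hedgehog ligand Dhh (at least 577-fold). Their caNIK levels ran from 39.8 ± 19.6 CPM for Dhh to 164 ± 9.27 CPM for Serpinb9b. The ryanodine receptor gene Ryr3 had 2 control reads and reached 444 ± 88.5 CPM, a ratio of 9410 with a counting interval of 2610 to 77700.

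Among the largest falls, endomucin (Emcn), a surface sialomucin of endothelium and stem cells, fell from 18.3 ± 3.59 to 0.171 ± 0.167 CPM. The potassium channel gene Kcng1 fell from 20.7 ± 4.13 to 0.242 ± 0.342 CPM, Lrrn4 from 13.4 ± 4.24 to 0.233 ± 0.126 CPM, and the Wnt antagonist Apcdd1 from 9.06 ± 0.165 to 0.161 ± 0.228 CPM. Log2 fold changes of the melanocortin receptor gene Mc5r, the collagen gene Col10a1 and Bok, of the Bcl-2 family, were -5.49 ± 0.45, -5.14 ± 0.54 and -5.03 ± 0.62. Each passed in edgeR's test, with adjusted p from 0.00061 (Mc5r) to 0.0075 (Apcdd1).

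**Figure D2:**
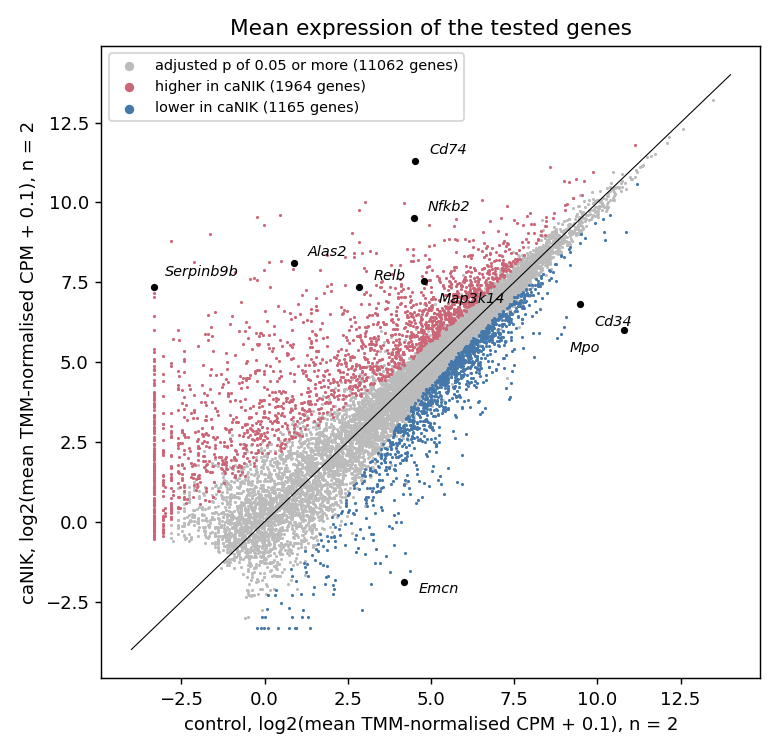
Mean TMM-normalised CPM of the 14191 tested genes in control (horizontal) and caNIK (vertical) libraries, both as log2 of the mean plus 0.1, n = 2 per group. Red points are the 1964 genes higher and blue points the 1165 genes lower in caNIK at an edgeR adjusted p under 0.05, and the line marks equal levels; genes with no control read stand in the column at the left edge.

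Genes of antigen presentation and of the interferon response were higher in caNIK HSPC. Cd74, the invariant chain that guides MHC class II molecules, rose from 22.7 ± 3.21 to 2490 ± 322 CPM, and the class II gene H2-Eb1 from 7.93 ± 1.32 to 1040 ± 136 CPM. Their log2 fold changes were 6.78 ± 0.22 and 7.04 ± 0.23, with 5.55 ± 0.25 for H2-DMb2, which helps load peptides (edgeR adjusted p from 4.7e-05 to 8.2e-05). Of 11 tested class II genes, 10 were higher and 0 lower (10 and 0 adjusted over the list alone), with a median log2 fold change of 5.55. In the class I list, 11 of 14 were higher and 0 lower (11 and 0 adjusted over the list alone; median 1.34). Among them were the peptide loading genes Tapbp (1.64 ± 0.14) and Tap1 (1.5 ± 0.15) and the transactivator Nlrc5 (2.38 ± 0.24). Of 50 interferon response genes, 45 were higher and 0 lower (45 and 0 adjusted over the list alone; median 1.76). The GTPase gene Gbp2 rose by 3.28 ± 0.22, and the antiviral genes Oasl2 and Isg20 each by 2.53, with SE 0.18 and 0.19. The class I and interferon lists share Tap1, Psmb8 and Psmb9, and the interferon and NF-kB target lists share Irf1 and Cxcl10. Those lists are therefore not fully separate evidence. Camera gave adjusted p = 1.4e-36 for class II, 4.0e-06 for class I and 1.2e-28 for interferon response genes. With an estimated correlation these were adjusted p = 0.43, adjusted p = 0.57 and adjusted p = 0.44. Without caNIK replicate 1, the interferon list had 39 higher genes and 1 lower.

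Of 36 tested inflammatory cytokines, chemokines and receptors, 10 were higher and 3 lower (13 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.088; median 0.55). The interleukin receptor genes Il18r1 and Il1rl1 rose by 5.90 ± 0.45 and 3.59 ± 0.30, and the chemokine gene Cxcl10 rose from 0.384 ± 0.483 to 72.8 ± 3.5 CPM. The list passed without control replicate 1 (camera adjusted p = 0.011; median 0.86) and without caNIK replicate 2 (0.017).

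Regulators and markers of stem cells were more often lower than higher. The chromatin protein gene Hmga2 fell by 2.32 ± 0.19 on the log2 scale, from 303 ± 37.7 to 60.5 ± 10.2 CPM, and the transcription factor gene Lmo2 by 1.32 ± 0.14, from 361 ± 2.3 to 144 ± 2.02 CPM (edgeR adjusted p = 0.00059 and 0.0013). Of 47 tested self-renewal regulators and markers, 16 were lower, 6 higher and 25 did not pass (22 and 8 adjusted over the list alone), with a median of -0.62. The 6 that rose were Gata2, a stem cell transcription factor that also acts in mast cells, Tgm2, and Ifitm1, Ifitm3, Ly6a and Ly6e, which are known to respond to interferon. The list was lower by camera (adjusted p = 6.9e-05), and adjusted p = 0.80 with an estimated correlation. Without caNIK replicate 1, 26 members were lower and the median was -1.06; in the median member caNIK replicate 1 lay 0.70 above replicate 2 on the log2 scale. Among 37 quiescence regulators, 6 were higher and 5 lower (7 and 8 adjusted over the list alone), with a median of -0.06 and camera adjusted p = 0.64. The list holds cell cycle inhibitors beside genes that drive the cycle, such as Cdk6, Ccnd1 and Myc. Opposite changes can cancel in its median and in camera, so neither measures quiescence. The retinoblastoma gene Rb1 rose by 1.29 ± 0.18 and Cdkn1a by 2.25 ± 0.27. That list held 10 lower members without caNIK replicate 1 and 3 without caNIK replicate 2, and its median turned to 0.04 without control replicate 2 and 0.03 without caNIK replicate 2.

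Genes of granulocyte-monocyte progenitors were more often lower than higher, a list call that rested on control replicate 2. The granule enzyme gene Mpo fell by 4.80 ± 0.43 on the log2 scale, from 1770 ± 1040 to 63.6 ± 3.34 CPM, and Csf3r, the G-CSF receptor, by 3.12 ± 0.26 (edgeR adjusted p = 8e-04 and 0.00068). Csf2rb2, an interleukin-3 receptor chain, rose by 3.35 ± 0.16. Of 26 tested members, 11 were lower and 3 higher (12 and 4 adjusted over the list alone), with a median of -1.20 and camera adjusted p = 0.011 (adjusted p = 0.86 with an estimated correlation). Control replicate 2 lay above replicate 1 by 0.91 in the median member. Without it the list no longer passed (camera adjusted p = 0.061; median -0.52), with 9 lower and 8 higher members. Lymphoid-primed progenitor genes had 5 lower and 3 higher of 26 (9 and 6 adjusted over the list alone; median -0.32; camera adjusted p = 0.44). The cytokine receptor gene Flt3 fell by 2.64 ± 0.32, whereas the T-lineage factor Tcf7 and the surface gene Ly6d rose by 3.17 ± 0.28 and 5.11 ± 0.44. That list passed as lower without control replicate 2 (camera adjusted p = 0.025; 10 lower, 4 higher) and without caNIK replicate 1 (0.011; 9 lower, 4 higher). It had 7 lower and 7 higher members without control replicate 1, and 4 and 6 without caNIK replicate 2. Its median was -0.14 and -0.55 without control replicates 1 and 2, and -0.87 and -0.05 without caNIK replicates 1 and 2.

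Erythroid genes were more often higher than lower. Alas2, the erythroid enzyme of heme synthesis, rose from 1.74 ± 0.189 to 272 ± 54.1 CPM (log2 fold change 7.28 ± 0.25), the anion exchanger gene Slc4a1 by 4.99 ± 0.48 and carbonic anhydrase Car2 by 2.56 ± 0.24 (edgeR adjusted p from 4.7e-05 to 0.00097). Of 25 tested members, 15 were higher and 0 lower (20 and 1 adjusted over the list alone), with a median of 2.48 and camera adjusted p = 5.8e-08 (adjusted p = 0.62 with an estimated correlation). The libraries of a group differed in these genes: in the median member control replicate 2 lay 1.62 above replicate 1, and caNIK replicate 1 lay below replicate 2 (difference -0.81). The list median was 1.74 and 3.76 without control replicates 1 and 2, and 2.78 and 1.92 without caNIK replicates 1 and 2. The members past the threshold also changed when 1 library was left out. Fewest were higher without caNIK replicate 2, fewer than with all libraries, and some of these fits had a lower member. Adult globin genes were listed at 0 in all 4 libraries; how reads that match several places were treated is not given in the sources used here, so this does not show that their transcripts were absent. Of 25 megakaryocyte and platelet genes, 6 were higher and 4 lower (9 and 4 adjusted over the list alone; median 0.70; camera adjusted p = 0.91). The integrin gene Itgb3 rose by 3.59 ± 0.36 and multimerin (Mmrn1) fell by 3.89 ± 0.28. Counts were 10 higher and 2 lower without control replicate 2, 3 and 2 without caNIK replicate 1, and 6 and 2 without caNIK replicate 2; the median was 0.26 without control replicate 1, 1.11 without control replicate 2 and 0.43 without caNIK replicate 1.

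Among cell cycle lists, that of inhibitors of cyclin-dependent kinases passed as higher, whereas mitosis and DNA replication genes did not pass as lists. Cdkn2a and Cdkn2b, the neighbouring inhibitor genes linked with senescence, rose from 0.220 ± 0.13 to 24.2 ± 1.16 CPM and from 0.392 ± 0.253 to 13.7 ± 2.74 CPM. With Cdkn1a they made 3 higher members among 7, against 1 lower, Cdkn1c (5 and 1 adjusted over the list alone). The list was higher by camera (median 1.47, adjusted p = 0.0068; adjusted p = 0.62 with an estimated correlation). Cdkn1c did not pass without control replicate 1 or without caNIK replicate 2, and the list median without the latter was 0.87. Of 40 mitosis and G2/M genes, 2 were higher and 0 lower (2 and 0 adjusted over the list alone; median 0.05; camera adjusted p = 0.83). These were the phosphatase gene Cdc25b (2.71 ± 0.20) and the proliferation marker Mki67 (1.06 ± 0.22). Without caNIK replicate 1 there were 8, and the list passed as higher (camera adjusted p = 0.013; median 0.30); without caNIK replicate 2, 1 was lower and the median was -0.22, and without control replicate 2 the median was 0.11. Of 40 DNA replication and G1/S genes, 5 were lower and 1 higher (0 and 1 adjusted over the list alone; median -0.21; camera adjusted p = 0.12). The member that rose was E2f2, from 46.6 ± 2.96 to 467 ± 168 CPM. The licensing factor gene Cdt1 fell by 0.85 ± 0.19 and Dtl, part of the ligase that degrades it, by 0.67 ± 0.16 (edgeR adjusted p = 0.022 and 0.025). Both lost the call without control replicate 2 (0.093 and 0.059), Cdt1 also without caNIK replicate 1 and Dtl without control replicate 1 (0.14). Lower members of this list numbered 1 without control replicate 1, 0 without control replicate 2, 1 without caNIK replicate 1 (4 higher) and 9 without caNIK replicate 2. In that last fit the list passed as lower (camera adjusted p = 0.0025; median -0.42), and without caNIK replicate 1 its median was -0.01.

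The lists of p53 target genes and of genes that promote cell death passed as higher by camera. They share Pmaip1, Fas, Bbc3, Bax, Apaf1 and Tnfrsf10b, and Fas is also among the NF-kB target genes. Pmaip1, the BH3-only protein Noxa, rose from 2.54 ± 0.22 to 101 ± 20.5 CPM, and the death receptor gene Fas from 0.584 ± 0.0183 to 31.3 ± 5.66 CPM. Zmat3, an RNA-binding p53 target, rose by 3.35 ± 0.20 (edgeR adjusted p from 8.4e-05 to 2e-04 over these 3). Of 29 tested p53 targets, 18 were higher and 1 lower (22 and 2 adjusted over the list alone), with a median of 1.23 and camera adjusted p = 9.4e-10 (adjusted p = 0.43 with an estimated correlation). Of 34 pro-apoptotic and necroptosis genes, 12 were higher and 3 lower (12 and 4 adjusted over the list alone), with 19 not past, a median of 0.38 and camera adjusted p = 0.0071 (adjusted p = 0.44 with an estimated correlation). Casp4, an inflammatory caspase gene, rose by 3.05 ± 0.23; the lower members were Bok, the necroptosis effector Mlkl and the TNF receptor Tnfrsf1a. Of 11 anti-apoptotic genes, 3 were higher, Birc2, Birc3 and Cflar, and 1 was lower, Bcl2 (3 and 1 adjusted over the list alone; median 0.20; camera adjusted p = 0.16).

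The 2 metabolic lists, oxidative phosphorylation and glycolysis, did not pass. In oxidative phosphorylation 0 of 52 genes were higher and 1 lower, Ndufa4 (-1.09 ± 0.16; 0 and 1 adjusted over the list alone; median -0.08; camera adjusted p = 0.16). Without caNIK replicate 2 that list had 2 lower members and passed (camera adjusted p = 0.0043; median -0.25), without caNIK replicate 1 it had 3 higher and a median of 0.05, and the median was -0.14 and -0.05 without control replicates 1 and 2. Of 27 glycolysis genes, 4 were higher and 2 lower (4 and 2 adjusted over the list alone), and the median of -0.07, the mean of 0.19 and the camera direction (lower, adjusted p = 1) differed in sign. The neuronal enolase gene Eno2 rose from 0.952 ± 0.0996 to 78.2 ± 16.9 CPM, whereas Hk2 and Pdk1 fell by 1.44 ± 0.17 and 1.16 ± 0.18. Lower glycolysis members numbered 4 without control replicate 1 (median -0.04) and 4 without caNIK replicate 1, and the median was -0.01 without caNIK replicate 2. Ribosome biogenesis genes and MYC targets had 2 lower and 0 higher of 42 (1 and 0 adjusted over the list alone; median -0.23). Both lower members, Myc (-0.85 ± 0.16) and Mycn (-1.10 ± 0.30; edgeR adjusted p = 0.043), are transcription factors that drive the list's other genes. The list was lower by camera (adjusted p = 0.011; adjusted p = 0.90 with an estimated correlation). It lost that call without control replicate 2 (0.073) and without caNIK replicate 1 (0.42; 1 higher), and Mycn lost its call without caNIK replicate 2 (0.056). Lower members numbered 4 without control replicate 1 and 12 without caNIK replicate 2; the list median was -0.15 without control replicate 2, -0.04 without caNIK replicate 1 and -0.49 without caNIK replicate 2.

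Of 32 adhesion and niche genes, 6 were higher and 3 lower (7 and 5 adjusted over the list alone; median -0.29; camera adjusted p = 0.36). Icam1, an NF-kB target, rose by 2.32 ± 0.19 and focal adhesion kinase Ptk2 by 1.89 ± 0.20; the stem cell sialomucin Cd34 fell from 718 ± 107 to 113 ± 41.5 CPM. Lower members numbered 5 without control replicate 2 and 10 without caNIK replicate 1. Of 29 immediate-early and handling stress genes, 6 were higher and 2 lower (6 and 2 adjusted over the list alone; median 0.33; camera adjusted p = 0.27). Ier5, Junb and Ppp1r15a rose by 2.65 ± 0.16, 2.05 ± 0.24 and 2.77 ± 0.38. The median member differed little between the control libraries (0.12 on the log2 scale, replicate 2 minus replicate 1). In Fos and Jun, control replicate 2 stood apart, with 1747 and 3006 reads against 150 and 329 in control replicate 1. Without it 5 members were higher and 1 lower. Counts were 8 and 5 without control replicate 1, 3 and 3 without caNIK replicate 1, and 5 and 0 without caNIK replicate 2. The median was 0.17 and 0.63 without control replicates 1 and 2, and 0.18 and 0.20 without caNIK replicates 1 and 2.

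Of the 6 marker lists of other cell types, 3 passed as higher, and the libraries of each group differed in several. Of 17 mature neutrophil genes, 11 were higher and 1 lower (12 and 1 adjusted over the list alone; median 2.53; camera adjusted p = 6.3e-06, and adjusted p = 0.57 with an estimated correlation). The granule gene Ngp and the alarmin gene S100a9 rose by 3.30 ± 0.19 and 3.36 ± 0.39, and Padi4, which modifies histones in neutrophils, fell by 3.12 ± 0.28. The neutrophil list median was 2.06 and 3.13 without control replicates 1 and 2, and 3.17 and 2.32 without caNIK replicates 1 and 2. Of 17 mast cell, basophil and eosinophil genes, 9 were higher and 1 lower (11 and 1 adjusted over the list alone; median 1.55; camera adjusted p = 3.9e-05, and adjusted p = 0.57 with an estimated correlation). The mast cell protease genes Tpsb2, Cma1 and Cpa3 rose by 6.45 ± 0.46, 5.76 ± 0.51 and 3.77 ± 0.39, Tpsb2 to 530 ± 246 CPM. The lower member was the eosinophil peroxidase gene Epx, counted 210 and 2631 times in control replicates 1 and 2 and 24 and 64 times in caNIK. Counts for that list were 8 higher and 4 lower without control replicate 1, 6 and 0 without caNIK replicate 1, and 10 and 0 without caNIK replicate 2; its median was 0.98 without control replicate 1, 2.38 without control replicate 2 and 0.94 without caNIK replicate 1. Of 20 monocyte, macrophage and dendritic cell genes, 6 were higher and 0 lower (6 and 0 adjusted over the list alone; median 1.30; camera adjusted p = 0.011, and adjusted p = 0.71 with an estimated correlation). Ms4a6c rose by 1.84 ± 0.18, the adhesion gene Vcam1, also on the NF-kB list, by 4.22 ± 0.55. The scavenger receptor gene Marco had 0 and 9 control reads against 102 and 164 in caNIK; its log2 fold change of 5.01 ± 1.01 was 4.09 without control replicate 1 and 10.03 without control replicate 2, which leaves no control read. Marco lost its call without caNIK replicate 2 (edgeR adjusted p = 0.059). That list had 8 higher and 2 lower members without control replicate 1, and 10 higher without control replicate 2.

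Lists of lymphocyte and stromal markers did not pass. Of 22 B cell and plasma cell genes, 6 were higher and 5 lower (8 and 6 adjusted over the list alone; median 0.47; camera adjusted p = 0.24). Spib, a transcription factor gene of B cells and dendritic cells, rose from 2.29 ± 0.582 to 154 ± 8.05 CPM, Igj by 4.45 ± 0.48 and Cd72 by 2.34 ± 0.29. Without control replicate 1 (0.047) and without caNIK replicate 2 (0.017) this list passed as higher, each with 3 lower members, and its median was 0.93 without control replicate 1. Of 28 T cell and NK cell genes, 3 were higher and 0 lower (2 and 0 adjusted over the list alone; median 0.51; camera adjusted p = 0.27). Cd6 rose by 4.16 ± 0.45 and the NK receptor gene Ncr1 was higher (edgeR adjusted p = 0.016), with 5 and 0 control reads against 338 and 67 in caNIK; Ncr1 lost its call without caNIK replicate 1 (0.074) and under limma-voom (0.064). In the median T and NK gene, control replicate 2 lay below replicate 1 (difference -1.69), and caNIK replicate 1 lay 1.20 above replicate 2. This list passed as higher without control replicate 1 (camera adjusted p = 6.9e-05; 12 higher) and without caNIK replicate 2 (0.0061; 7 higher), and had 6 higher and 2 lower members without control replicate 2 and 1 and 1 without caNIK replicate 1; its median was 1.51 and 0.20 without control replicates 1 and 2, and -0.11 and 1.07 without caNIK replicates 1 and 2. Of 22 endothelial and stromal genes, 2 were lower and 0 higher (1 and 0 adjusted over the list alone; median -0.13; camera adjusted p = 0.41). They were Emcn and Sox18, the latter with 54 and 89 control reads against 10 and 1 in caNIK, and Sox18 lost its call without caNIK replicate 2 (edgeR adjusted p = 0.082). Control replicate 2 lay 1.59 above replicate 1 in the median member. Without it 6 genes were higher and the list median was 0.92; without control replicate 1 the list passed as lower (camera adjusted p = 0.034), and without caNIK replicate 2 it had 1 lower member and a median of 0.14.

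**Figure D3:**
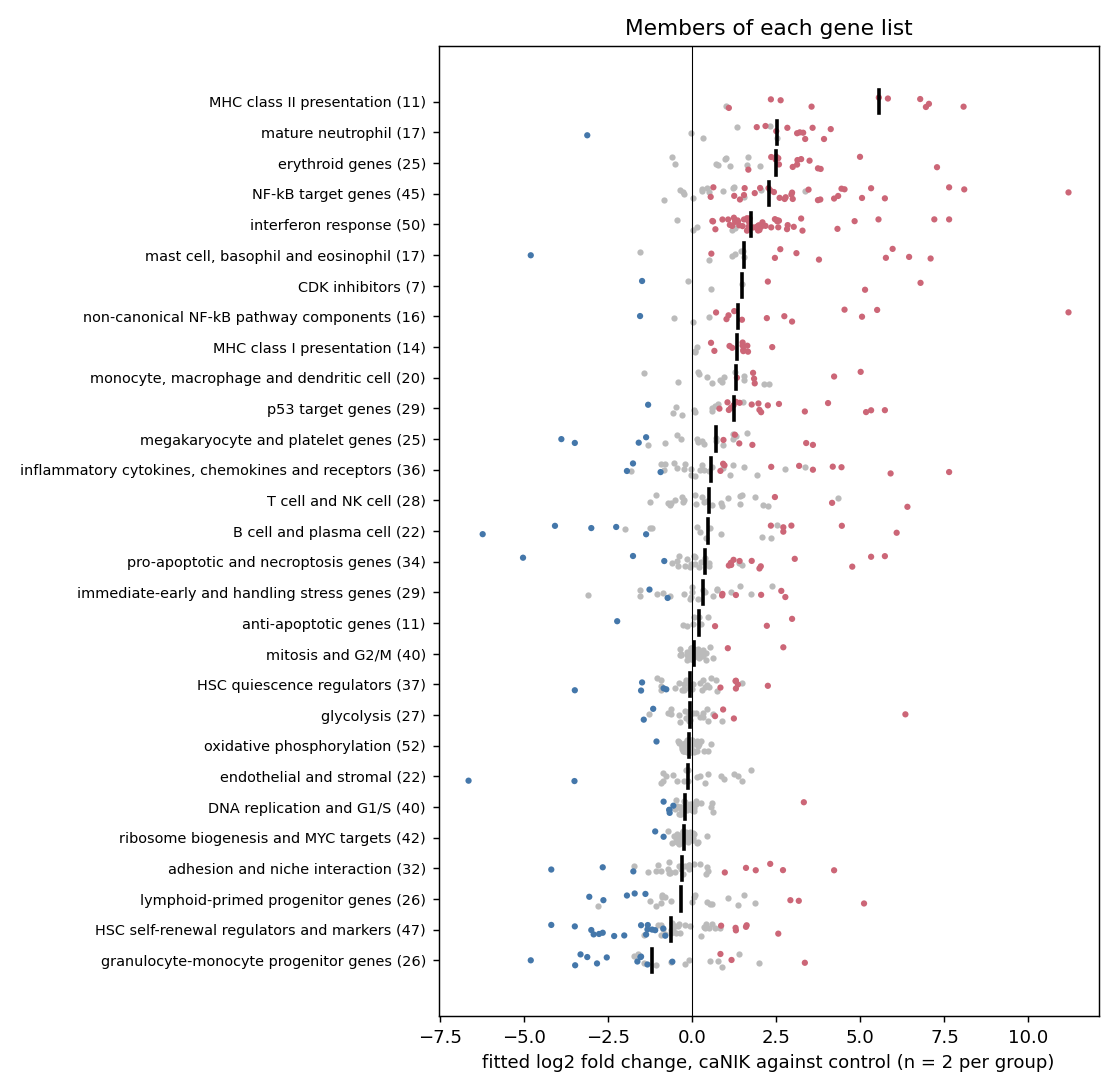
Fitted log2 fold change, caNIK against control (n = 2 per group), of every tested member of the 29 gene lists, with the number of tested members in brackets. Red and blue points are members higher and lower at an edgeR adjusted p under 0.05, grey points did not pass, and black bars are list medians, from 5.55 for MHC class II presentation to -1.20 for granulocyte-monocyte progenitor genes.

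In all, 15 of 29 lists passed in camera with the preset correlation, 12 higher and 3 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.43), with 3 at an unadjusted p under 0.05, and the self-contained test fry called 7, of which 6 were among the 15 and 1, anti-apoptotic genes (fry adjusted p = 0.022), was not. Calls were also lost where the estimated correlation lay near the preset 0.01. It was -0.01 for pro-apoptotic and necroptosis genes, and 0.03 for NF-kB target genes and for p53 target genes. For these lists a high correlation does not account for the loss. The setting with an estimated correlation rests on the few residual degrees of freedom of 4 libraries. Its failures here therefore do not separate lists that moved from lists that did not. Reads of Xist and of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in all 4 libraries (Xist 21187 to 38009 reads, Ddx3y 527 to 1191). Xist is transcribed in female cells and the Y-linked genes in male cells, so each library held reads of both sexes and n counts libraries rather than animals; whether this came from pooled animals was not tested. The balance differed in control replicate 1, with Xist at 1970 CPM and Uty at 5.34 CPM, against 903 and 17.7 CPM in control replicate 2, 1190 and 21.2 in caNIK replicate 1 and 1160 and 13.2 in caNIK replicate 2.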

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

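All settings in this part were chosen before the data were examined. The count of 3129 genes past the threshold stayed within 1.5 times under 13 of 14 alternatives, from 2604 to 4260, and between 2604 and 3174 when 1 library was left out. Testing against a fold change of 1.5 gave 1815 genes, 1357 higher and 458 lower, since that test asks for a larger change. Of the 3129 genes, 2947 passed with library totals only, 3104 with DESeq2 and 3044 with limma-voom. Leaving out caNIK replicate 2 kept 2264 calls, the fewest over the left-out libraries; the sign held for 3112 of the 3112 of these genes that were tested. The share of calls that were higher was 62.8%, with 57.2% under upper-quartile factors and 57.6% under library totals, and the median log2 fold change of all genes moved by at most 0.06 in size. Map3k14 kept its call under all 13 alternatives, with log2 fold changes from 2.62 to 2.86.

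With the replicate number as a block, 4260 genes passed, 2494 higher and 1766 lower, and 17 lists; inflammatory cytokines (adjusted p = 0.043) and T and NK genes (0.042) were added. Deviations of same-numbered libraries correlated at 0.21 across genes. The second principal component set replicate 1 (35.2 in control, 25.5 in caNIK) apart from replicate 2 (-37.4 and -23.4). In the median erythroid gene replicate 2 lay above replicate 1 in both groups, and in the median T and NK gene below it. The mast cell list went opposite ways in the groups. A replicate effect shared by the groups, which the main model leaves out, stays open. With 2 pairs and no label for what a number shares, the numbers do not establish a pairing.

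In place of 15 lists, 0 passed with camera's correlation estimated per list, also among lists whose estimate lay near the preset. That setting has little power with so few libraries. The self-contained test fry, which asks whether a list's genes move on balance rather than whether they exceed other genes, called 7. It kept 6 of the 15 and added anti-apoptotic genes (fry adjusted p = 0.022). List calls numbered 15 under the other scalings and the other filter, and 14 to 20 when 1 library was left out. In all, 248 of 290 list tests stayed on their side of the threshold, 27 lost a call, 15 gained one and 0 turned. A turn was counted only where the list passed in at least 1 of the fits compared. Medians of some lists that did not pass did change sign when 1 library was left out, as given with the lists. For the 88 named genes, 1131 of 1142 tests stayed, 11 lost the call, in 6 genes, and 0 turned. Beyond the left-out libraries given with the lists, Mycn lost its call under library totals (0.051) and with at least 5 CPM in 2 libraries (0.053). Counts of list members moved by over 1.5 times, or from or to 0, in 16 lists with the replicate block, 15 when testing against a fold change of 1.5, 12 with the loosest filter and 6 with DESeq2, and in 0 to 4 under the other scalings and filters and limma-voom. In place of 3 higher T and NK genes there were 10 with the block, 9 with the loosest filter and 6 with DESeq2, and in place of 3 lower adhesion genes 11, 10 and 6. In place of 2 lower ribosome biogenesis genes there were 10 with the block, 5 with upper-quartile factors and 0 against a fold change of 1.5, which also gave 9 lower self-renewal genes in place of 16. The cause was not tested. With 2 libraries a group, the simulations recovered 36.4% of 2-fold changes, so genes that did not pass cannot be read as unchanged.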

Other observations

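Genes and lists in this part that are not among the fixed ones were chosen after their values were seen, and the tests of explanations for the last 3 patterns, as well as their medians and quartiles without 1 library, were chosen only after the results were seen. Aire, the transcription factor known for switching on tissue-restricted genes in thymic epithelium, rose from 0.893 ± 0.0576 to 625 ± 160 CPM (SD, n = 2; log2 fold change 9.45 ± 0.31; edgeR adjusted p = 4.7e-05). Tnfrsf11a, the receptor RANK, rose by 5.50 ± 0.32. Among 6 co-stimulatory and checkpoint ligands, 5 were higher and 0 lower, with Icosl at 328 ± 12.7 CPM against 3.57 ± 0.164 in control, Pdcd1lg2 at 68.7 ± 27.4 against 8.03 ± 0.385 and Cd274 at 79.3 ± 17.2 against 25.9 ± 3.13. Cd86 did not pass (0.69 ± 0.40, adjusted p = 0.27). Tph1, the serotonin synthesis enzyme used by mast cells, rose from 0.218 ± 0.234 to 518 ± 25.8 CPM, and the interleukin-9 receptor gene Il9r from 6.40 ± 0.854 to 310 ± 40.5 CPM.

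Genes known from fetal stem and progenitor cells were read in control HSPC and most were lower in caNIK. Of 7 such genes, 6 were lower and 0 higher, with a median log2 fold change of -1.17; without control replicate 2, 5 were lower and 1 higher. Lin28b fell from 28.5 ± 0.979 to 9.25 ± 5.19 CPM, Igf2bp2 from 34.7 ± 1.18 to 9.74 ± 1.57, Igf2bp3 from 142 ± 4.99 to 63.2 ± 2.19 and Arid3a from 78.1 ± 16.3 to 40.5 ± 6.61; Hmga2 and Mycn were the others, and Igf2bp1 did not pass. All 3 embryonic globin genes tested were higher in caNIK: Hba-x was at least 60.1-fold higher, and Hbb-bh1 had 0 and 2 control reads against 102 and 141.

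Of 8556 genes near-silent in control, with at most 3 reads over both libraries, 308 (3.6%) had at least 10 reads in each caNIK library, against 32 of 7820 (0.409%) the other way. General background or genomic DNA as the whole source is argued against by olfactory and vomeronasal receptor genes, of which 0 of 1429 (0%, exact 95% upper bound 0.258%) were switched on, against 4.32% of the others (interval 3.86% to 4.82%). A part of the rise from background stays open. Reads over the 1429 rose from 10 and 28 in control to 87 and 110 in caNIK (0.061 and 0.077 per gene), to which choosing genes by low control counts adds. Chosen by low caNIK counts instead, 1421 receptor genes had 70 and 40 reads in control against 52 and 22 in caNIK. That gap was smaller, so the choice of genes does not account for the whole rise. Reads over other near-silent genes not switched on rose from 433 and 1574 to 6513 and 4951. All 1452 receptor genes rose from 97.5 and 76.8 to 140 and 121 CPM. Most of their reads (2601 and 2505 in caNIK) came from receptor genes with more than 3 control reads, so this total does not measure background. Thymic epithelial cells as the whole source are argued against by the level of 11 epithelial structural genes, which share none with the fixed lists and summed to 35.4 and 25.2 CPM in caNIK (at most 4.91% of Aire) and 117 and 37.8 CPM in control, with no read of Krt5, Krt14 or Krt15; their fold changes decide nothing, since the median of -0.95 was 0.47 without control replicate 1, and Trp63 (0 and 1 control reads, 234 and 81 in caNIK, edgeR adjusted p = 0.0036) and Foxn1 (0 and 0, 16 and 0) go the other way. A candidate explanation in which AIRE acts on its targets stays open: of 20 genes cited as AIRE-dependent in thymic epithelium, 17 were near-silent and 2 (11.8%, interval 1.46% to 36.4%), Csn2 and Tg, were switched on (Fisher's exact test, two-sided, p = 0.12), too few to decide. NIK activity itself and a changed mix of cells were not tested for this pattern.

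Erythroid, neutrophil and mast cell genes were higher and granulocyte-monocyte progenitor genes lower by camera with the preset correlation, but not with an estimated one (adjusted p = 0.62, 0.57, 0.57 and 0.86), and the last list did not pass without control replicate 2 (0.061; 9 lower, 8 higher). A lower share of the main population would raise those other types that were in the sort. The median log2 fold change of the erythroid list exceeded that of the endothelial and stromal list by 2.61 (permutation over genes, two-sided, p = 1e-05, the smallest 100000 resamples can give), and by 1.78 to 2.90 without 1 library. The endothelial and stromal median of -0.13 turned to 0.92 without control replicate 2 and 0.14 without caNIK replicate 2. This comparison cannot decide, since the sort may have held few endothelial or stromal cells, and their list holds Emcn, also a stem cell gene. Genes are not independent replicates (estimated correlation 0.82 in the erythroid list), and the comparison was chosen after the erythroid rise was seen. The neutrophil and mast cell lists were not compared in this way, and a lower share of the main population stays open. A different mix of progenitors in the sorted cells may account for the erythroid median of 2.48 (1.74 without control replicate 1 to 3.76 without control replicate 2). Such a mix cannot be told apart from changes inside cells, since bulk counts hold no value per cell and the sort gate is not given in the sources used here. Within the erythroid list, Alas2 rose by 7.28 ± 0.25, while Klf1 did not pass (1.64 ± 0.55, edgeR adjusted p = 0.081). The caNIK genotype as the cause of such a shift was not tested apart from this.

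MHC class II genes and Cd74 were the highest-rising fixed list by median, and antigen-presenting cells in the sort would carry them. Mature B cells as the whole source are argued against by 6 identity genes, which had a median log2 fold change of -1.22 (-2.29 without caNIK replicate 1, -0.69 without caNIK replicate 2) and an upper quartile of 0.10, below the lower quartile of 2.48 of the class II list, also without any 1 library (upper quartile at most 0.41); Cd79b was the most abundant at 44.5 ± 8.06 CPM, against 2490 CPM for Cd74, 5 of the 6 reached 1 CPM in control, and Ms4a1 goes the other way (2.51 ± 0.85, edgeR adjusted p = 0.082; 14 and 8 control reads, 89 and 27 in caNIK). Monocytes, macrophages or dendritic cells cannot be told apart from a change inside progenitors: their list had a median of 1.30 and an upper quartile of 1.84, but without control replicate 2 its upper quartile of 2.63 exceeded the class II lower quartile of 2.32. Its highest members in caNIK were Vcam1 at 261 ± 109 and Lyz2 at 186 ± 123 CPM; 17 of its 22 genes reached 1 CPM in control and 3 are in another list. NIK activity as the cause was not tested apart from these.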
